A study of Mus musculus with 10 samples.

How the data were processed

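Gene expression was measured by bulk RNA sequencing in leukemia initiating cells, the transformed B cell precursors of mice that carry the RFP/RET fusion transgene. Per the labels' protocols, the cells were sorted by flow cytometry from the spleen of pups, and total RNA was isolated with a column kit for DNA and RNA. There were 5 libraries from pups given PBS and 5 from pups given Poly(A:U), a synthetic double-stranded RNA that is a ligand of Toll-like receptor 3. Per the series' design text each library came from a separate pup.

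The authors deposited, for each library, estimated counts of reads per transcript, with the TPM value and the effective length of each transcript, per the file headers. The submitters' processing notes name DRAGEN, edgeR 3.38.4 and the mouse build mm10. The counter's settings, the annotation release and whether strand was used are not given in the sources used here. The authors' deposited table of the whole series holds a normalized signal for 13699 genes, named as edgeR-normalized CPM. Its columns sum to between 945642 and 1043413, so the values are CPM after scaling factors, and whole reads could not be recovered from them.

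Each file listed 142333 transcripts. They were assigned to genes with the GENCODE M21 annotation of the same build, which left out 538 transcripts holding between 0.046% and 0.0695% of the reads of a library. Estimated counts were summed over the transcripts of each gene and rounded to whole numbers. Library totals ran from 17859006 to 22587871 estimated reads. On the log2 scale, CPM from these sums correlated with the authors' deposited signal across genes at r = 0.997 or more in each library, genes not being independent replicates, and 9 of the authors' genes had no match. Reads of near-identical copies, such as processed pseudogenes, ribosomal protein genes and the interferon-induced Oas and Gbp families, were shared out by the authors' estimation, so the levels of single members are uncertain. Overlapping and antisense genes cannot be told apart where strand was not used. The human part of the transgene is not in the annotation used here, and the value of Ret is that of the mouse gene.

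Genes were kept by edgeR's filterByExpr at its defaults, a minimum count of 10 and a floor near 0.49 CPM in 5 libraries, which left 13729 genes. Groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, robust dispersion and treatment as the only term. Adjusted p-values are Benjamini-Hochberg, two-sided, with a threshold of 0.05, and log2 fold changes are Poly(A:U) minus PBS. Standard errors were derived from the F statistic, and 95% intervals from the t distribution with the fit's degrees of freedom. These errors cover the spread between pups and the counting error together.

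Before the data were examined, 18 lists of pathway genes and 10 lists of markers of other cell types were written down. Lists with at least 5 tested members were compared with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Adjustment was over the pathway lists and over the marker lists separately. The marker lists of natural killer cells, megakaryocytes, mast cells and sex-linked genes had fewer than 5 tested members with all 10 libraries and are given as values. Some alternatives tested them. A list score is the mean log2 CPM of its tested genes in a library, centred on the mean of the 10 libraries.

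The genes named in the text were chosen by a rule fixed in advance. It took called genes of at least 5 CPM with all 5 Poly(A:U) libraries on one side of the PBS mean. Where fewer than 5 passed in a direction, it took the 5 with the smallest unadjusted p instead. Gene segments of antigen receptors, pseudogenes and gene models named only Gm or Rik were left out. From each list it took called members or, where there were none, the 2 with the smallest unadjusted p, and it always included Tlr3, Ret, Ifit1, Isg15, Irf7, Cdkn1a, Mki67, Pax5, Il7r, Igll1 and Myc. One more gene that it always included is not reported here. Other genes named were chosen after their values were seen.

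The tests were first tried on simulated data, with counts drawn for the 13729 genes of Poly(A:U) against PBS from their observed means, dispersions and library sizes, in 5 sets with 200 changed genes each. The edgeR test called 36.1% of genes changed 1.5-fold, 66% of genes changed 2-fold and 87.6% of genes changed 4-fold, and 5% of its calls were unchanged genes. Of the calls of DESeq2's Wald test, 16.7% were unchanged genes, and of those of limma voom with quality weights, 4.9%. A list moved by 0.4 on the log2 scale was called in 5 of 5 sets by camera at either correlation and by fry. Genes varied independently in these sets, which differs from the correlated lists of the real libraries.

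Alternatives were other normalization factors, no filter and a filter of 10 CPM in 5 libraries, the replicate number as a block, each library left out in turn, and counts rebuilt from TPM and effective length. One further surrogate variable (sva 3.50.0), limma on the log2 of the authors' deposited signal with a pseudocount of 1 or 0.1 (genes at 1 or more in 5 libraries, or no filter), DESeq2 1.42.0 and limma voom with quality weights were also run. The deposited names of PBS 1, PBS 2 and PBS 3 share a start that no label explains, and the names of PBS 4 and Poly(A:U) 5, of PBS 5 and Poly(A:U) 1, and of Poly(A:U) 3 and Poly(A:U) 4 share a number pair by pair. No label explains these numbers either. Leaving out the first 3 was planned. Using their name as a covariate, leaving out PBS 4 and Poly(A:U) 5, both together, and a fit with all shared parts of the names as terms were added after seeing the data. In the last of these the treatment is estimated within 2 pairs of libraries, PBS 4 with Poly(A:U) 5 and PBS 5 with Poly(A:U) 1. With the name start as a covariate it is estimated from PBS 4 and PBS 5 against Poly(A:U). The name is then estimated from PBS 1 to PBS 3 against PBS 4 and PBS 5. With the covariate and without PBS 4 and Poly(A:U) 5, the treatment rests on PBS 5 alone. PBS 1 to PBS 3 were also compared with the other 7 libraries, the name start being the only term.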

Results

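The series holds RNA-seq libraries of leukemia initiating cells from the spleen of 13-day-old mouse pups with the RFP/RET transgene, which drives B cell precursor leukemia. Cells were collected 7 days after treatment with 50 µl of PBS (5 pups) or 20 µg of Poly(A:U) (5 pups), and the stated question was how Poly(A:U) affects these cells. Libraries held between 17859006 and 22587871 estimated reads. Genes with at least 10 reads numbered between 13396 and 14702 in 9 libraries and 16006 in PBS 4. Mitochondrial transcripts took from 2.93% to 5.53% of reads.

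All 10 libraries carried the transcripts of a B cell precursor. Cd79a, a chain of the B cell receptor complex, averaged 3248 ± 433 CPM (SD, n = 10), Ighm 3656 ± 614 CPM, and the surrogate light chain genes Igll1 and Vpreb1 1345 ± 290 and 1257 ± 245 CPM. Pax5, the transcription factor of B cell identity, averaged 1212 ± 269 CPM and the recombinase gene Rag2 166 ± 23 CPM. Mouse Ret averaged 169 ± 36 CPM. Kit, a progenitor receptor, was near the floor at 1.36 ± 0.55 CPM.

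No single gene passed edgeR's test between Poly(A:U) and PBS 7 days after treatment. Ret stood at 178 ± 47 CPM in PBS and 160 ± 23 CPM in Poly(A:U) (SD, n = 5 each), a log2 fold change of -0.15 ± 0.18 (SE). Tlr3, the receptor of double-stranded RNA, was low in both groups, 1.29 ± 0.38 CPM in PBS and 0.90 ± 0.52 CPM in Poly(A:U). Of the B lineage genes, Igll1 had a log2 fold change of -0.05 ± 0.19, Pax5 of -0.26 ± 0.17 and Il7r, the interleukin-7 receptor, of -0.23 ± 0.10. The proliferation gene Mki67 gave -0.07 ± 0.20, Cdkn1a, a p53 target that halts the cell cycle, 0.26 ± 0.13, and Myc 0.68 ± 0.35 on the log2 scale.

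Of 13729 genes, edgeR's quasi-likelihood test gave 0 with an adjusted p below the threshold, the smallest adjusted p being 0.677. At an unadjusted p below 0.05 there were 1002 genes, 564 higher and 438 lower in Poly(A:U), where chance alone gives about 686. The groups did not overlap for 111 genes (0.81%, against 0.79% by chance). Among the 9097 genes with a mean of at least 10 CPM, the median half-width of the 95% interval was 0.245 on the log2 scale, a 1.18-fold change, and the interval excluded a 2-fold change for 97.3% of them. DESeq2's Wald test called 13 genes (4 higher, 9 lower), and limma voom with quality weights 932 (488 higher, 444 lower). Without PBS 5 the edgeR test called 18 genes, and it called 0 without any other single library.

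Among the genes with the smallest unadjusted p, none of which passed edgeR's test, Dlx1, a homeobox gene on chromosome 2 of mm10 (71528113 to 71533981), had 18.1 ± 4.4 CPM in PBS and 28.5 ± 1.7 CPM in Poly(A:U), a log2 fold change of 0.65 ± 0.14 (SE). The protein-coding gene AC149090.1, on an unplaced scaffold, had 55.7 ± 15.9 and 108 ± 18.5 CPM, a log2 fold change of 0.95. Fastkd3 and Tefm, which act on mitochondrial RNA, gave 0.67 and 0.57, and Tmem128 gave 0.48. On the lower side, the macrophage gene Mpeg1 had 13.5 ± 6.4 and 4.69 ± 0.88 CPM, Anxa2 8.36 ± 6.84 CPM in PBS and 1.06 to 1.91 CPM in Poly(A:U), the nucleoside transporter gene Slc29a4 11.8 ± 1.4 and 7.97 ± 0.66 CPM, and Herpud1, a gene of the endoplasmic reticulum stress response, 170 ± 16 and 133 ± 7.2 CPM. The Y-linked gene Eif2s3y had 32.3 ± 28.6 CPM in PBS and 0.18 ± 0.25 CPM in Poly(A:U), and among the PBS libraries it was at 42.7 CPM or more in PBS 1 to PBS 3 and at most 2.90 CPM in PBS 4 and PBS 5. In PBS 5 Anxa2 was at 0.94 CPM, below the Poly(A:U) libraries, and Mpeg1 at 4.20 CPM, within their range. The other PBS libraries were above the Poly(A:U) range for both genes, PBS 4 being the highest at 19.5 and 21.5 CPM. Each of these 10 genes had an adjusted p of 0.677 in edgeR's test. DESeq2's Wald test called 7 of them, with adjusted p of 0.00502 for AC149090.1, 0.00900 for Anxa2 and Eif2s3y, 0.0120 for Mpeg1, 0.0271 for Herpud1, 0.0296 for Slc29a4 and 0.0434 for Dlx1. Its other 6 calls, named after their values were seen, were Rxfp1 and Rsrp1, higher in Poly(A:U), and Cxcr4, Fcer1g and the Y-linked Kdm5d and Ddx3y, lower.

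**Figure D1:**
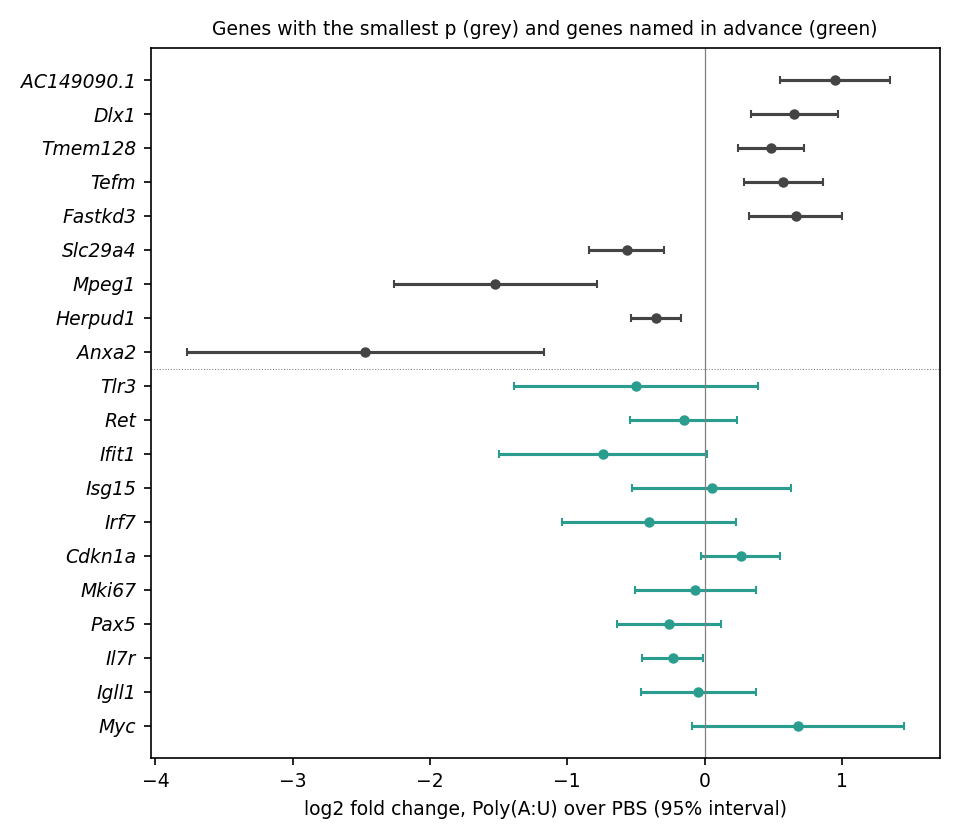
Log2 fold changes of Poly(A:U) over PBS with 95% intervals (points and bars, 5 libraries per group) for the genes with the smallest unadjusted p, Eif2s3y left out for scale, and for 11 genes named in advance. The first set lies between -2.47 for Anxa2 and 0.95 for AC149090.1, and the intervals of 10 of the 11 genes named in advance include 0.

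Interferon-stimulated genes, which type I interferon induces in antiviral defence, were lower as a list in Poly(A:U). Of 35 tested genes 31 had a negative log2 fold change, with a median of -0.40, and camera gave an adjusted p of 9.8e-07. With an estimated correlation it was lost (adjusted p = 0.590 with an estimated correlation). The median was -0.24 without PBS 1 (adjusted p = 1.86e-04, camera), -0.26 without PBS 3 (7.66e-05) and -0.18 under a filter of 10 CPM (0.00397). Oasl1 had 11.9 ± 5.1 CPM in PBS and 6.73 ± 1.16 CPM in Poly(A:U), Ifitm3 3.06 ± 1.23 and 1.72 ± 0.32 CPM, Ifit1 2.67 ± 1.01 and 1.59 ± 0.53 CPM, and Irf7 11.2 ± 3.6 and 8.41 ± 3.53 CPM (SD, n = 5 each). Isg15 was at 5.44 ± 0.31 and 5.63 ± 2.72 CPM. Oasl1 was at 12.8 CPM or more in PBS 1 to PBS 3. In PBS 4 (7.74 CPM) and PBS 5 (5.52 CPM) it did not exceed the highest Poly(A:U) library (8.56 CPM). Ifitm3 and Ifit1 lay above all Poly(A:U) libraries in PBS 4 (2.55 and 2.70 CPM) and below them in PBS 5 (1.13 and 0.99 CPM). The interferon-gamma and antigen presentation list was lower too, with 22 of 28 genes negative, a median of -0.21 and an adjusted p of 9.4e-04 by camera (adjusted p = 0.477 with an estimated correlation). In it Tap1, the peptide transporter, had 148 ± 17.5 and 115 ± 8.1 CPM, and B2m 949 ± 154 and 780 ± 64 CPM.

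Genes of DNA replication and growth factor signalling were higher as lists. In the G1/S and DNA replication list 20 of 24 genes had a positive log2 fold change, with a median of only 0.07 and an adjusted p of 0.0127 by camera (adjusted p = 0.882 with an estimated correlation). Pcna, the replication clamp, had 448 ± 46 and 512 ± 34 CPM, and Slbp 142 ± 14.5 and 165 ± 11.7 CPM. In the list of RET, MAPK and immediate-early genes 16 of 24 were positive, with a median of 0.32 and an adjusted p of 0.0271 by camera (adjusted p = 0.561 with an estimated correlation). Ier2, an immediate-early gene, had 69.1 ± 28.6 and 103 ± 15.4 CPM, and Spry4, a feedback inhibitor of MAPK signalling, 6.34 ± 1.82 and 9.40 ± 2.54 CPM. Ier2 was at 41.7 to 55.8 CPM in PBS 1 to PBS 3, while PBS 4 (104 CPM) and PBS 5 (95.1 CPM) lay within the Poly(A:U) range. Spry4 lay within that group's range in PBS 4 (9.32 CPM) and below it in PBS 5 (6.51 CPM). No member of any list passed edgeR's test over all genes, DESeq2's test called Herpud1, Mpeg1 and the Y-linked Eif2s3y, Kdm5d and Ddx3y among list members, and fry called none of the 18 pathway lists in one direction. Without PBS 1 to PBS 3, the only libraries with the shared name start, none of these 4 calls held: the interferon list had a median of 0.06 (adjusted p = 0.35, camera), the interferon-gamma list 0.02, the G1/S list -0.15 and the RET and MAPK list 0.08. With all shared parts of the library names as terms, which leaves the treatment to 2 pairs of libraries, the RET and MAPK call held (median 0.20, adjusted p = 0.0361, camera), the interferon lists did not pass (0.276 and 0.108) and the G1/S list was lower (median -0.12, adjusted p = 0.0203). Both calls were lost in that fit with an estimated correlation (adjusted p = 0.770 with an estimated correlation). Leaving out PBS 1, PBS 2 or PBS 3 singly ended the G1/S call (adjusted p = 0.0582, 0.235 and 0.143, camera; medians 0.04, 0.01 and 0.03), while without PBS 4 its median was 0.21 (1.76e-10). Leaving out PBS 1, PBS 2, Poly(A:U) 1, Poly(A:U) 2 or Poly(A:U) 5 ended the RET and MAPK call (0.0582, 0.0729, 0.0600, 0.0700 and 0.0777), with medians of 0.26, 0.22, 0.30, 0.19 and 0.20. The filter of 10 CPM ended it too (median 0.17, adjusted p = 0.117, camera).

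The other 14 pathway lists did not pass camera. B cell precursor identity had 21 of 26 genes negative (median -0.09, adjusted p = 0.0697, camera), with Sox4 at 470 ± 45 CPM in PBS and 388 ± 26 CPM in Poly(A:U) and Rag2 at 151 ± 16 and 182 ± 17 CPM. The p53 targets had 15 of 22 positive (median 0.08, adjusted p = 0.0700, camera), with Mdm2 at 68.0 ± 13.1 and 84.0 ± 3.7 CPM and Cdkn1a at 17.7 ± 3.4 and 21.3 ± 2.1 CPM. For heat shock and sorting stress the median was 0.09 and the mean -0.03, of opposite sign, with camera upward (adjusted p = 0.0580). Without PBS 4 the precursor (adjusted p = 1.25e-04), p53 (0.0371) and heat shock (7.0e-04) lists passed camera, as they did without Poly(A:U) 1 (0.0411, 0.0168 and 0.0322) and without Poly(A:U) 3 (0.0482, 0.0307 and 0.0307). The BCL-2 and caspase list, which holds the regulators of cell death, had a median of 0.01, with Mcl1 at 299 ± 33 and 332 ± 14 CPM and Bok at 18.2 ± 4.3 and 23.3 ± 2.6 CPM. G2/M genes had a median of 0.03, with Cenpa at 131 ± 19 and 149 ± 13 CPM, oxidative phosphorylation 0.04, ribosomal proteins 0.07, cholesterol synthesis 0.02, and NF-kB targets -0.03. Mature B cell genes had a median of -0.10, genes of TLR and RNA sensing -0.05, with Ticam1, the TLR3 adaptor, at 28.8 ± 5.6 and 23.5 ± 0.7 CPM, and glycolysis and hypoxia -0.04. The adjusted p of these 9 lists lay between 0.291 and 0.909 by camera. Without PBS 4 the G2/M (adjusted p = 7.5e-04), mature B cell (0.00448) and NF-kB (0.0153) lists passed, as did NF-kB without Poly(A:U) 3 (0.0387), and oxidative phosphorylation (0.00140) and ribosomal proteins (9.3e-06) without Poly(A:U) 5.

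A single gene in each of a pair of these lists had an adjusted p below the threshold when adjusted over the list alone by edgeR, against 0 over all genes. In the stem and progenitor list (9 genes tested, median -0.27, adjusted p = 0.133, camera) it was Kit, at 1.79 ± 0.36 CPM in PBS and 0.92 ± 0.25 CPM in Poly(A:U). Cd34 of that list was at 20.5 CPM in PBS 4 and at most 1.42 CPM in each of the other 9 libraries. The list passed camera without PBS 4, PBS 5, Poly(A:U) 1, Poly(A:U) 2 or Poly(A:U) 3 (adjusted p = 0.0432, 0.0493, 0.0322, 0.0269 and 0.00465). In the unfolded protein and stress response list (18 genes tested, median 0.07, adjusted p = 0.310, camera) it was Herpud1, while Ddit3 of the same list had 12.7 ± 2.0 and 17.8 ± 4.1 CPM.

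**Figure D2:**
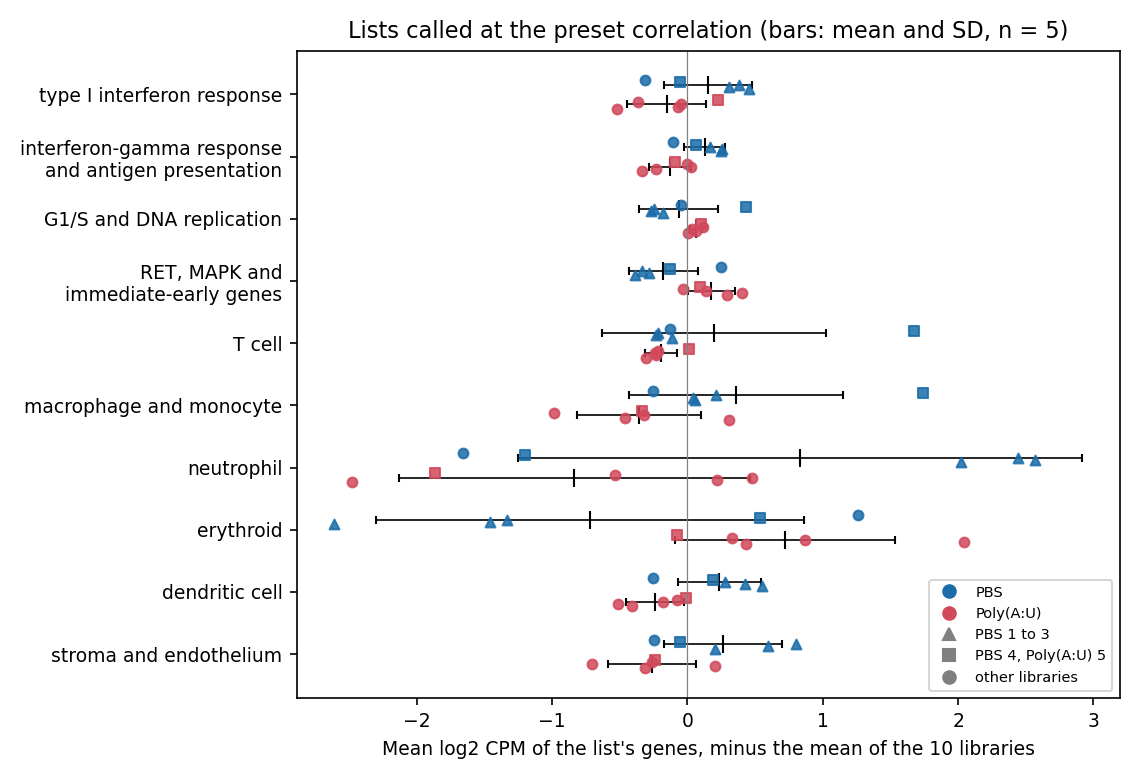
Scores per library (mean log2 CPM of the list's tested genes, centred on the 10 libraries) for the 4 pathway and 6 marker lists called at the preset correlation, with the mean and SD of each group (n = 5). For the interferon list PBS 1 to PBS 3 lie at 0.305 or above and PBS 5 at -0.31, inside the Poly(A:U) range of -0.52 to 0.226.

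Of the marker lists of cells other than B cell precursors 6 were called, and each of these calls was lost without PBS 1 to PBS 3 or without PBS 4. Neutrophil genes were lower in Poly(A:U), 14 of 14 negative with a median of -2.17 (adjusted p = 2.2e-06, camera; adjusted p = 0.212 with an estimated correlation). S100a8 was at 130 to 224 CPM in PBS 1 to PBS 3 and at 4.54 to 53.03 CPM in the other 7 libraries, and Mpo, the granule peroxidase, at 17.4 to 24.7 CPM and at most 2.87 CPM. Erythroid genes were higher, 18 of 19 positive with a median of 0.87 (adjusted p = 2.5e-07, camera; adjusted p = 0.212 with an estimated correlation), and the beta-globin gene Hbb-bs was at 55.5 to 187 CPM in PBS 1 to PBS 3 and 515 to 5281 CPM in the others, PBS 5 among them at 5003 CPM. The erythroid median was 2.18 without PBS 5, 0.56 without PBS 1 and 0.33 without Poly(A:U) 2, the call being kept, and with all shared parts of the names as terms the list was lower (median -0.70, adjusted p = 4.8e-05, camera; adjusted p = 0.516 with an estimated correlation). Macrophage genes were lower, 12 of 15 negative with a median of -1.09 (adjusted p = 4.5e-04, camera; adjusted p = 0.212 with an estimated correlation). C1qa was at 33.7 CPM in PBS 4 and at most 4.31 CPM in each other library, and Mpeg1 was the 1 gene called over this list alone.

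T cell genes were lower, 8 of 9 negative with a median of -0.36 (adjusted p = 0.0319, camera; adjusted p = 0.227 with an estimated correlation), and Cd3e was at 55.8 CPM in PBS 4, 2.84 CPM in Poly(A:U) 5 and at most 0.54 CPM elsewhere. The T cell median was -0.02 without PBS 4, -0.34 without Poly(A:U) 3, and between -1.33 (without PBS 2) and -0.74 (without Poly(A:U) 4) without each other library. Dendritic cell genes (4 of 5 negative, median -0.16, adjusted p = 0.0422, camera) and stromal genes (4 of 6 negative, median -0.33, adjusted p = 0.0465, camera) were lower, each with an adjusted p of 0.212 with an estimated correlation. Of the lists too small to test, the natural killer gene Klrb1c had 6.53 ± 0.77 and 6.63 ± 2.42 CPM, the platelet integrin gene Itgb3 9.58 ± 2.94 and 10.2 ± 2.4 CPM and the mast cell gene Hdc 1.59 ± 0.75 and 1.01 ± 0.39 CPM. The Y-linked gene Ddx3y was at 43.4 CPM or more in PBS 1 to PBS 3 and at most 4.84 CPM in the other 7 libraries, and Xist, transcribed from the inactive X chromosome, at most 0.34 CPM and at least 116 CPM. Without PBS 1 to PBS 3 the neutrophil, erythroid, dendritic and stromal calls did not hold, and without PBS 4 the T cell (adjusted p = 0.391, camera), macrophage (median 0.13, adjusted p = 0.115) and stromal (median -0.34, as large as before, adjusted p = 0.156) calls did not. The dendritic call was also lost without PBS 1, PBS 2, PBS 3, Poly(A:U) 1, Poly(A:U) 2 or Poly(A:U) 5 (adjusted p between 0.0551 and 0.114, camera), its median being -0.09 without PBS 1, -0.06 without PBS 3, -0.26 without PBS 5 and -0.24 without Poly(A:U) 2, and the stromal call without any single library but PBS 5 and Poly(A:U) 2 (between 0.0514 and 0.468), with medians of -0.11 without PBS 2, -0.19 without PBS 3, -0.15 without Poly(A:U) 3 and -0.17 without Poly(A:U) 4.

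**Figure D3:**
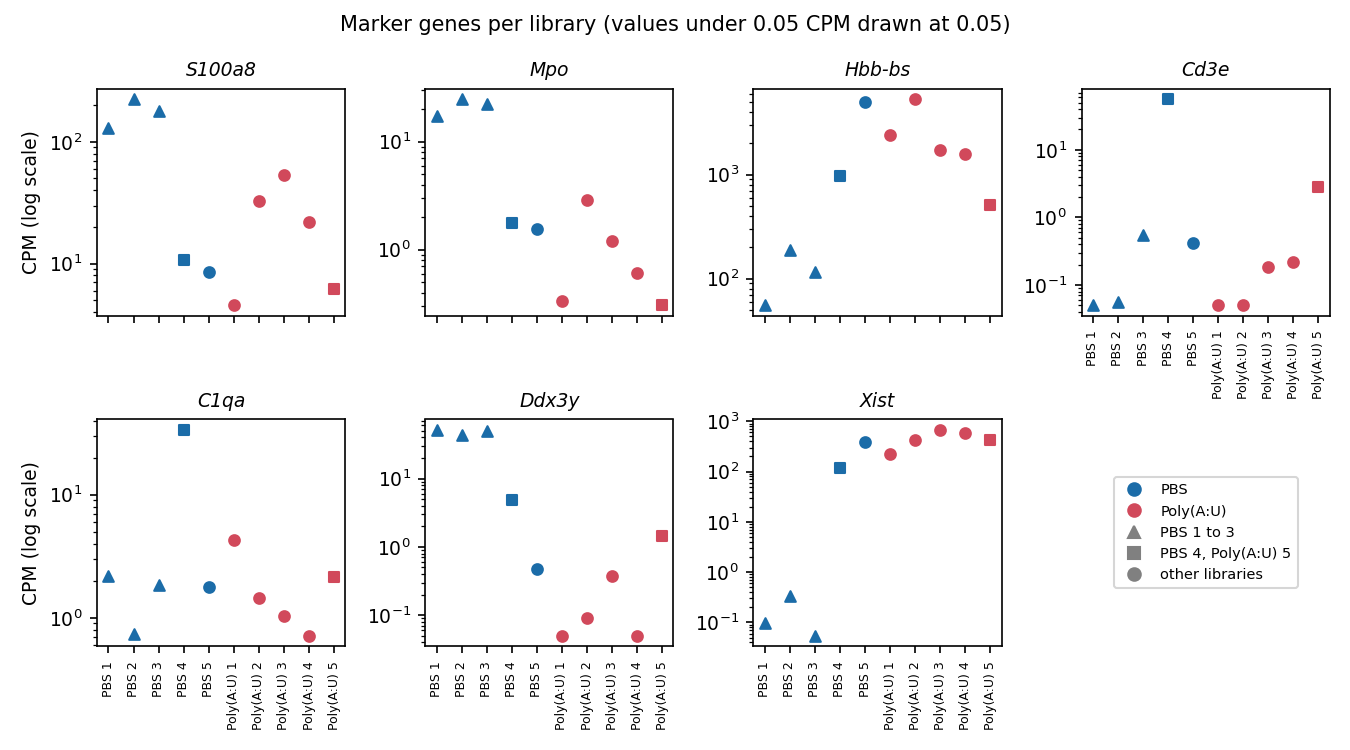
CPM on a log scale of 7 genes in each of the 10 libraries (blue PBS, red Poly(A:U); triangles PBS 1 to PBS 3, squares PBS 4 and Poly(A:U) 5). S100a8, Mpo and Ddx3y are highest in PBS 1 to PBS 3, where Hbb-bs and Xist are lowest, while Cd3e and C1qa are highest in PBS 4, at 55.8 and 33.7 CPM.

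The first 2 principal components did not fully part the treatments. The first (35.9% of the variance) set PBS 4 apart, at 82.5 against at most 25.3 for the others, and the second (21.1%) set PBS 1 to PBS 3, at -26.7 or below, and PBS 4, at -17.5, apart from PBS 5 at 22.5 and the Poly(A:U) libraries at 2.15 to 32.3. The median correlation of PBS 4 with the other 9 libraries was r = 0.940 over tested genes, against 0.966 or more for each other library. PBS 4 correlated most with Poly(A:U) 5 (r = 0.959) and PBS 5 with Poly(A:U) 1 (r = 0.987, against 0.986 with Poly(A:U) 3), each a pair that shares a number in its names. Genes are not independent replicates, and no pair of libraries was a duplicate of another within sampling noise. With the shared name start of PBS 1 to PBS 3 as a covariate, edgeR called 77 genes between PBS 1 to PBS 3 and the other PBS libraries, PBS 4 and PBS 5 (18 higher and 59 lower in PBS 1 to PBS 3), and 0 for Poly(A:U). Without PBS 1 to PBS 3 it also called 0 for Poly(A:U), with 2 PBS libraries left. The shared name start occurs in PBS libraries only.

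**Figure D4:**
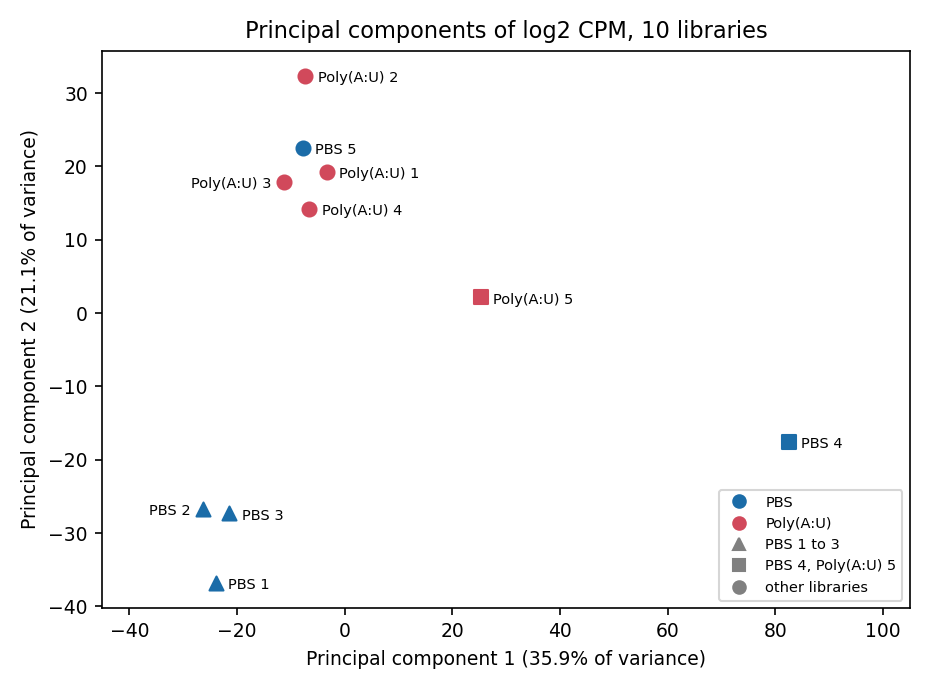
Principal components 1 and 2 of log2 CPM over 13729 genes, in units of the component scores, with 1 point per library (blue PBS, red Poly(A:U)). PBS 4 lies at 82.5 on component 1 and at -17.5 on component 2, and PBS 5 lies at 22.5 on component 2 among the Poly(A:U) libraries.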

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

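All tests of explanations here were chosen only after the result was seen. A value was singled out where 1 library of a group of 5 lay far from the rest, with a gap to its nearest neighbour above 0.71 of the group's range. This happened for 29 of 206 groups of values, where chance gives about 1 in 20, and 11 of them were in PBS 4, 9 in Poly(A:U) 5 and 9 in other libraries.

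PBS 4 had 16006 genes with at least 10 reads and a median correlation of 0.9395 with the other libraries. Its list scores were 1.674 for T cells, 1.742 for macrophages, 0.371 for glycolysis and hypoxia, -0.259 for B cell precursor identity and -0.384 for mature B cells, and it had 13.03 CPM of Trac, 6.873 CPM of Cd4, 20.47 CPM of Cd34 and 7.077 CPM of Aldoc. Poly(A:U) 5 stood apart from its group, at lower levels, for Trac (1.879 CPM), Cd4 (0.7865 CPM), Cd34 (0.9175 CPM) and the T cell score (0.013), and its scores were 0.334 for G2/M and -0.251 for oxidative phosphorylation. It also had the highest Mki67 (1606 CPM), Myc (111.5 CPM) and Spry4 (13.81 CPM) of its group. Genes with under 0.3 CPM in the 8 libraries other than Poly(A:U) 5 and over 1 CPM in PBS 4 numbered 255 coding genes and 1 lincRNA, and their median level in Poly(A:U) 5 was 9.3% of that in PBS 4.

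For PBS 4, genomic DNA is argued against by olfactory and vomeronasal receptor genes, at 11.5 CPM in PBS 4 and 9.45 to 14.6 CPM in the others. T cells of the mouse, which a sort for B cell precursors is meant to remove, are argued against by Cd3d, at 0.27% of the level of Cd3e, although 11 of the 19 T cell markers listed were over 1 CPM and over 2-fold above the 8 libraries other than Poly(A:U) 5. Reads from another organism may be the source, since coding genes were newly seen more often than lincRNAs (odds ratio 151.4, lower 95% limit 26.98). The same step gave at most 2 coding genes and 0 lincRNAs in each of those 8 libraries, too few for a ratio. Over all coding genes and lincRNAs, expressed ones included, the ratio of being seen in each was 25.7 to 28.8. That is an unlike set of genes, so an excess beyond the usual one of coding genes cannot be judged. Processed pseudogenes took 6.15% of reads in PBS 4 and 3.00% to 3.60% in the others. No biological explanation other than T cells was tested.

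PBS 1 to PBS 3 differed from the other 7 libraries in 600 genes called by edgeR. Dilution of the leukemia cells by other cells stays open for the 361 lower genes. Their median log2 difference was -0.64 (-0.63 without PBS 4), against 0.19 (0.15) for the 26 genes of the B cell precursor list. The precursor list thus did not fall as a whole. The 361 genes were picked as lower in this same comparison, which enlarges their fall, so the medians are not alike. The lowest precursor gene was at -0.30 (-0.33). Without PBS 4 it fell by more than 50% of the lower genes' median, past the limit set for arguing against dilution. PBS 4 and PBS 5 were given PBS like PBS 1 to PBS 3, so the treatment by itself does not part them from PBS 1 to PBS 3. A scale over all tested genes ran from the Poly(A:U) libraries (0) to PBS 1 to PBS 3 (1). PBS 5 lay on it at 0.068, PBS 4 at -0.017 and each Poly(A:U) library at 0.077 to 0.212. Between PBS 1 to PBS 3 and these 2 PBS libraries edgeR called 77 genes with the name start as a covariate. Only these 2 PBS libraries lie outside the name start, and each shares a number with a Poly(A:U) library. A part of the treatment in the difference thus cannot be judged. Sex of the pups, which the labels do not give, stays open. Of the 600 genes 16 were on X or Y, and the share among all tested genes was not counted. Since Xist and the Y-linked genes part the same libraries, sex and the name start cannot be told apart. No Poly(A:U) library had the Xist and Y-linked levels of PBS 1 to PBS 3, so sex is also tied up with the treatment groups.

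The other values that stood apart were Slc29a4 (9.316 CPM) and B2m (1223 CPM) in PBS 2. In PBS 5 they were Tnfaip3 (82.28 CPM), Mdm2 (91.05 CPM) and Itgb3 (14.71 CPM). In Poly(A:U) 2 they were Birc5 (116.9 CPM), Hspa8 (1301 CPM) and Igfbp7 (1.249 CPM), and in Poly(A:U) 1 Dnajb4 (7.171 CPM).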

How the results depend on the processing

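The name start as a covariate, the omission of PBS 4 and Poly(A:U) 5, and all shared name parts as terms were chosen after seeing the data; the other alternatives were planned. The count of 0 genes by edgeR (1002 at an unadjusted p below 0.05) held under the other scaling and filters, the surrogate variable, rebuilt counts and limma on the authors' signal. It was 13 by DESeq2, 932 by limma voom with quality weights and 0 to 18 with each library left out, the 18 being without PBS 5. With the covariate and without PBS 4 and Poly(A:U) 5 the treatment rests on PBS 5 alone, so no count of genes or lists is given for that fit. Named genes, none of which edgeR called with all 10 libraries, stayed uncalled in 1084 pairs of gene and setting and were called in 41, and in 736 and 4 with each library left out. No called value changed sign, and with the covariate and without PBS 4 and Poly(A:U) 5 the sign of 21 of 69 uncalled named genes did, as did 23 of 74 with the name parts as terms.

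Against 4 pathway lists, camera called 0 with an estimated correlation, fry 0, no filter 7 and the 10 CPM filter 3. The surrogate variable gave 10, omission of PBS 1 to PBS 3 gave 1 and the covariate 2. Omission of PBS 4 and Poly(A:U) 5 gave 10, and the name parts as terms 3. Leaving out each library gave 2 to 11. Against 6 marker lists the counts were 0 with an estimated correlation, 0 by fry, 8 with no filter and 5 with DESeq2 size factors. They were 2 with the 10 CPM filter, and 3 and 3 on the authors' signal at either pseudocount. Without PBS 1 to PBS 3 the count was 2, with the covariate 3, and without PBS 4 and Poly(A:U) 5 it was 2. It was 4 with the name parts as terms, and 3 to 7 with each library left out. The 10 CPM filter tests fewer marker genes, and the cause was not tested for the others. The counts cover unlike lists, since some lists reached 5 tested members only in some settings. With no filter the natural killer, mast cell and sex-linked lists were among the calls. The sex-linked list was also called without PBS 5 and without each Poly(A:U) library (adjusted p from 1.256e-05 to 6.882e-04, camera). The median correlation of PBS 4 was 0.9395 by Pearson and 0.9585 by Spearman.

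Lists that turned direction with a call before or after, with camera's adjusted p, did so only in the settings that remove PBS 1 to PBS 3 or their name. Without these libraries they were type I interferon (0.3525), G2/M (8.719e-04), G1/S (0.05049), neutrophil (0.06119), erythroid (0.9048) and dendritic (0.9048). With the covariate they were type I interferon (0.5105), G2/M (1.584e-04), G1/S (0.008338), neutrophil (0.04445), erythroid (0.815), dendritic (0.8568) and stroma (0.9414). With the covariate and without PBS 4 and Poly(A:U) 5 they were type I interferon (0.3706), RET and MAPK (0.7079), glycolysis (0.02272), neutrophil (0.03049) and erythroid (0.1961). With the name parts as terms they were type I interferon (0.2757), G1/S (0.02027), ribosomal proteins (0.02027) and erythroid (4.795e-05). The cause was not tested. PBS 4, 1 of the 2 PBS libraries that decide G2/M where that list turned, had the highest G2/M score (0.449). With the covariate and without PBS 4 and Poly(A:U) 5, the median of the G2/M list was -0.09. With an estimated correlation no list passed for Poly(A:U) against PBS in any setting where camera was run, each library left out included. Depth limits genes near the floor of 0.49 CPM.

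With the replicate number as a replicate block, 0 genes were called by edgeR (943 at an unadjusted p below 0.05), 5 pathway lists and 6 marker lists. The labels do not say whether the numbers pair the samples. Deviations of same-numbered libraries correlated across genes at 0.021, 0.14, 0.136, -0.133 and -0.183. These lie inside the range of the other pairs (-0.298 to 0.367), so they give no sign of pairing but cannot exclude it.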

Other observations

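The comparison of PBS 1 to PBS 3 with the other 7 libraries, PBS 4 and PBS 5 among them, and its splits into 3 and 7, were chosen only after the data were seen. With the shared name start as the only term edgeR called 600 genes, 239 higher and 361 lower in PBS 1 to PBS 3. Without PBS 4 it called 824, of which 590 were among the 600, and with each library left out between 40 and 942, the fewest without PBS 1 (40), PBS 2 (60), PBS 3 (107), Poly(A:U) 3 (312) and Poly(A:U) 4 (333) and the most without Poly(A:U) 5 (942). By camera the lists of type I interferon (median log2 difference 0.69, adjusted p = 4.74e-13), interferon-gamma, B cell precursor, neutrophil (2.99, 5.82e-16), dendritic and stromal genes were higher, and those of G1/S (-0.29, 4.08e-09), G2/M, heat shock, RET and MAPK (-0.38, 0.0105) and erythroid genes (-3.21, 5.82e-16) lower. Of these calls interferon-gamma held with an estimated correlation (adjusted p = 0.0426 with an estimated correlation) but not without PBS 4 (0.0567), and the others did not hold (0.0662 to 0.425). The stromal call was lost without PBS 4 (median 0.54, adjusted p = 0.132, camera).

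The genes named here were chosen after their values were seen. Egr1, an immediate-early transcription factor gene, averaged 31.3 CPM in PBS 1 to PBS 3 and 97.0 CPM in the other 7 (log2 difference -1.63 ± 0.15, SE, adjusted p = 5.21e-04, edgeR). Myc averaged 31.8 and 84.2 CPM (-1.41 ± 0.15) and Ier2 48.7 and 102 CPM (-1.07 ± 0.13). Arrdc3 went the other way, at 132 and 35.3 CPM (1.90 ± 0.10, adjusted p = 1.64e-06, edgeR). Interferon genes did not move as one, since Oasl1 averaged 15.4 and 6.70 CPM (1.20 ± 0.16) and Ifi27 141 and 82.7 CPM (0.77 ± 0.10), while Rsad2 averaged 0.83 and 16.8 CPM (-4.34 ± 0.65). Each of these 7 genes was also called without PBS 4. Of the 120 ways to split the libraries into 3 and 7, 100 were drawn, the real one included. For the 600 genes 1 of 100 gave as many (highest other 3). The grouping follows the library names and was set down before the data were examined. The comparison itself was prompted by the data, so this share cannot exclude chance. For the 7 pathway lists 34 of 100 gave as many (highest other 13) and for the 4 marker lists 15 of 100 (highest other 5), so chance cannot be excluded for these.

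Without PBS 5, edgeR called 18 genes between Poly(A:U) and PBS, 9 higher and 9 lower. The PBS group was then PBS 1 to PBS 3 with PBS 4. These calls thus cannot be told apart from differences of those libraries that do not come from the treatment. Among the higher were Vegfa, the angiogenic growth factor gene, at 48.1 CPM in 4 PBS libraries and 89.3 CPM in Poly(A:U) (log2 fold change 0.89 ± 0.12), the splicing kinase gene Clk1 at 78.1 and 134 CPM, and Wsb1 at 53.8 and 96.7 CPM. The lower ones included the myeloid genes Mpeg1 (-1.76), Fcer1g (-2.07) and Ccl6 (-2.74), and the Y-linked gene Uty. With PBS 5 in the comparison edgeR called none of the 18, and DESeq2 called Mpeg1, Fcer1g, Anxa2 and Dlx1 among them.

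Of the tests here, those on the interferon list were chosen only after the result was seen, and the counts over splits into 5 and 5 were planned. The lower type I interferon list in Poly(A:U) had a median of -0.40, and with the shared name start as a covariate it was 0.0608. That fit sets PBS 4 and PBS 5 against Poly(A:U), as the omission of PBS 1 to PBS 3 does (0.06), so it adds no separate evidence, and the name start stays open. The treatment stays open too. Without PBS 1 to PBS 3 the list score of 2 PBS libraries minus that of 5 Poly(A:U) libraries was -0.03 (exact two-sided permutation p = 0.9048, smallest possible 0.0476). Over all 10 libraries the score of PBS minus that of Poly(A:U) was 0.307 (exact permutation p = 0.159). That of PBS 1 to PBS 3 minus that of the other 7 was 0.541 (exact permutation p = 0.0167).

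Of the 126 ways to split the 10 libraries into 5 and 5, 100 were drawn, the real one included. For edgeR's 0 genes all 100 splits gave as many (highest other 2), which any split does for a count of 0, so it says nothing on chance. For DESeq2's 13 genes 14 of 100 gave as many (highest other 733), for the 4 pathway lists 72 of 100 (highest other 11) and for the interferon list, whose -log10 p by camera was 7.26, 16 of 100 (highest other 25.067), so chance cannot be excluded for these. For the 932 genes of limma voom 2 of 100 gave as many (highest other 1237), and for the 6 marker lists 1 of 100 (highest other 5). Each share is under 0.05, but without correction over the results tried on these splits, so chance is not excluded for this pair. Among the 14 drawn splits that keep PBS 1 to PBS 3 together, as the real one does, 2 reached 932 genes and 1 reached 6 lists, and these splits are too few for a share under 0.05. The split with 1237 genes is among them, and the 86 splits that part them gave at most 1 gene. This points to a structure of the libraries that follows the shared name start, and neither the 932 genes nor the 6 marker lists can be assigned to the treatment.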
